A study of Mus musculus with 6 samples.

How the data were processed

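Total RNA from embryonic spleens of mice at E13.5 was measured on 6 Affymetrix whole-transcript mouse gene arrays, 3 from Tlx1 heterozygous and 3 from Tlx1 homozygous embryos per the labels. The values used here are the deposited intensities, 1 per probe set and array, which were made with GCRMA per the submitters' processing notes. GCRMA corrects the background of each probe with a model of its sequence, normalizes the arrays to each other and summarises the probes of a probe set. Its version, the probe set definition and the genome build are not given in the sources used here. The values lie on a linear scale, with array medians of 106 to 110 and maxima of 22276 to 23785, and no log or centring by gene is visible in them. A log2 scale had been foreseen as the usual output of GCRMA, with the logarithm to be taken of value + 1 otherwise, and that second form was used.

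The table holds 35512 probe sets. A table of the platform's annotation named 21789 of them with 1 gene symbol and 1621 with several, and 12102 were unnamed in it. Entrez gene identifiers were looked up in a RefSeq gene table of the assembly GRCm38.p6, where 21698 were found, and no symbol changed. Probe sets with several symbols or none stayed out of the comparison of genes. Probe sets were kept where the log2 value was at least 4 (an intensity of 15) on at least 3 of the 6 arrays, which left 20424 named probe sets. For each gene the probe set with the highest mean over the 6 arrays was used, which gave 18710 genes. Of these, 951 had several kept probe sets. Among the 140 called genes with several, another probe set was called in the opposite direction for 5 and was not called for 91.

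The comparison was homozygous minus heterozygous. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on log2(intensity + 1), over all 6 arrays with no covariate. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(intensity + 1) scale, and the added 1 pulls the fold changes of dim genes toward 0. Background calls per probe were not used here, so a low intensity is given as measured and is no proof of expression.

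Fixed gene lists, 29 in number, were tested for a shared direction against the other genes with camera at a correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists with at least 5 measured members. Camera was repeated with an estimated correlation, and fry was run on the same lists. List counts are also given with the adjustment made over the list alone. The gene lists, the tests, the filter and the rule for naming genes were chosen before the data were examined. That rule names Tlx1, then the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, skipping predicted and clone names. From each list it names up to 4 called members with the largest change, or the 2 with the smallest p where none passed. It also names a set of retinoic acid and spleen genes, among them Aldh1a2, Rdh10, Cyp26b1, Cyp26a1, Dhrs3, Rarb, Crabp1, Crabp2, Nkx2-5, Nkx3-2, Wt1, Tcf21 and Barx1. A named gene outside these parts is said to be chosen after its values were seen.

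Alternatives were another filter on low values, other choices of probe set per gene, quantile normalization of the deposited values, centring each array on its median, other variance models, array weights, the replicate number as a block, and refits that left out each array in turn. A fit with the level of the Y-linked genes as a covariate and a cyclic loess between arrays were added after the data were seen. The fitting steps were tested on simulated data with 18710 genes and the spread of these arrays. There, 6% of genes changed by 0.25 on the log2 scale were recovered, 94% of those changed by 0.5 and 100% of those changed by 1 or 2. Of the 163 genes called in that simulation 13 were unchanged, and 2 of 100 random lists of 25 unchanged genes fell below a camera p of 0.05. Genes were drawn independently there, so this does not cover lists whose members are correlated. Only 50 genes were changed per size, which made the adjusted threshold stricter, so the recovered shares need not hold for these data. The number of arrays limits the precision of each value.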

Results

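Gene expression was profiled in spleens of mouse embryos at E13.5, in mid-gestation, when the spleen is a small mesenchymal organ beside the stomach and pancreas. Tlx1 encodes a homeobox transcription factor that the spleen needs in order to form, and 3 arrays of Tlx1 heterozygous spleens were set against 3 arrays of Tlx1 homozygous spleens. The labels name the zygosity and not the allele, and homozygous is read here as homozygous for the altered Tlx1 allele. The series title poses the question as one of TLX1 and retinoic acid signalling. Array medians lay between 106 and 110 intensity units. Log2 values correlated across genes at 0.995 to 0.997 within groups and at 0.989 to 0.993 between groups, and the first principal component, with 61.9% of the variance, placed all heterozygous arrays on one side and all homozygous arrays on the other. The labels do not say whether the replicates were separate embryos or pools, and the sex-linked genes given below do not decide it. The p-values measure only the spread between these samples, which may be technical. Scan dates were not analysed here, so a difference in processing aligned with genotype was left unexamined. Means are given with SD over 3 arrays per group, and log2 fold changes, homozygous minus heterozygous, with their standard error (SE).

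Tlx1 itself fell 3.87-fold in homozygous spleens. Its intensity was 750 ± 65.3 (SD, n = 3) in heterozygous and 193 ± 19.9 (SD, n = 3) in homozygous samples, a log2 fold change of −1.95 ± 0.09 (SE) with an adjusted p of 1.3e-05 in limma. The groups did not overlap. Tlx1 was measured by 1 probe set, and whether that probe set lies inside the altered part of the gene is not known here, so the remaining signal in homozygous spleens is no measure of functional transcript.

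Among 18710 genes, 1951 were higher and 1227 lower in homozygous spleens, together 17.0% of those tested. Most changes were small, with a median size of 0.37 on the log2 scale, and 58 genes changed at least 2-fold, 13 up and 45 down. The deepest fall was that of Apela, which encodes a secreted ligand of the apelin receptor, from 496 ± 42.1 to 29.7 ± 1.34 (SD, n = 3), a log2 fold change of −4.01 ± 0.08. Falls were also large for the secreted protein gene Kazald1 (log2 fold change −3.34) and the G protein alpha subunit gene Gna14 (−3.30). Kazald1 lies next to Tlx1 in the gene order, and whether its fall follows from that position was not tested. The Popeye domain genes Popdc3 (−2.94) and Bves (−2.62) fell as well. Also in the leading 12 falls were the Wnt antagonist Frzb (−2.75), the membrane peptidase gene Mme (−2.59), the iron exporter gene Slc40a1 (−2.36), the collagen gene Col8a1 (3.99-fold lower) and the transcriptional cofactor gene Eya1, from 379 ± 6.29 to 94.1 ± 2.37 (SD, n = 3). Clca3a1 (−2.18) and Clca3a2 (−2.09) complete these falls and are uncertain as separate results, since the paralogs are near-identical in sequence.

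Rises were smaller than falls. Cpa1, a digestive carboxypeptidase of the exocrine pancreas, rose from 534 ± 290 to 1664 ± 103 (SD, n = 3), a log2 fold change of 1.77 ± 0.30 with a wide spread between the heterozygous arrays, and its adjusted p of 0.00793 became 0.0575 with a variance trend and a robust fit together. Shisa3, a membrane adaptor that dampens Wnt and FGF receptors, rose by 1.70 ± 0.07. The collagen VI chains Col6a1 and Col6a2 rose by 1.17 and 1.14, the GABA receptor subunit gene Gabrb2 by 1.11, Fibin by 1.08, the imprinted zinc finger gene Zim1 by 1.07, the homeobox gene Alx1 by 1.06 and the BMP family ligand gene Gdf6 by 1.01. Prp2 (1.13) and the olfactory receptor genes Olfr767 (1.19) and Olfr59 (1.01) belong to multigene families and are uncertain. Olfr59 was dim, at 19.5 ± 1.75 against 41.2 ± 12.5 (SD, n = 3), and its adjusted p was 0.052 with the Y-linked gene level as a covariate.

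Of the 3178 called genes, 3170 had groups that did not overlap, as had 38.3% of all genes tested, where chance gives 10%. Calls were 61.4% higher, and this share depended on the scaling, at 67.3% after quantile normalization, 72.6% after median centring and 48.3% after cyclic loess (1092 higher, 1168 lower). Across genes, which are not independent replicates, the log2 fold change fell with mean level (Spearman's rho −0.39). Counts also moved when 1 array was left out. Without homozygous replicate 1 there were 699 higher and 499 lower genes, and without heterozygous replicate 2 820 and 556. Without heterozygous replicate 1 there were 1046 and 643, and without homozygous replicate 3 987 and 835. They were 1697 and 834 without heterozygous replicate 3, and 2319 and 1244 without homozygous replicate 2. Fewer samples enter these fits, so a lower count need not come from the array left out. The Y-linked genes Eif2s3y, Kdm5d and Uty were brighter on heterozygous arrays 1 and 3 (Eif2s3y 600 and 735) than on the other 4 arrays (391 to 417), and Xist was dimmer there (901 and 812, against 1478 to 1857). Uty and Xist were chosen after their values were seen. Every array gave signal for Xist, a transcript of female cells, and for Y-linked genes of male cells. The lowest of these values, 206 for Kdm5d on heterozygous array 2, lay well above the filter floor of 15. That floor is not the background of these probe sets, which was not tested. On heterozygous array 2 and the homozygous arrays Kdm5d was nearly flat (206 to 228), which background alone could also give. These values therefore do not decide between single embryos, pools of 1 sex and pools of both sexes. Heterozygous arrays 1 and 3 may hold a larger male share than any homozygous array, so sex makeup may differ between the groups. With the Y-linked level as a covariate 1140 genes were higher and 507 lower.

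**Figure D1:**
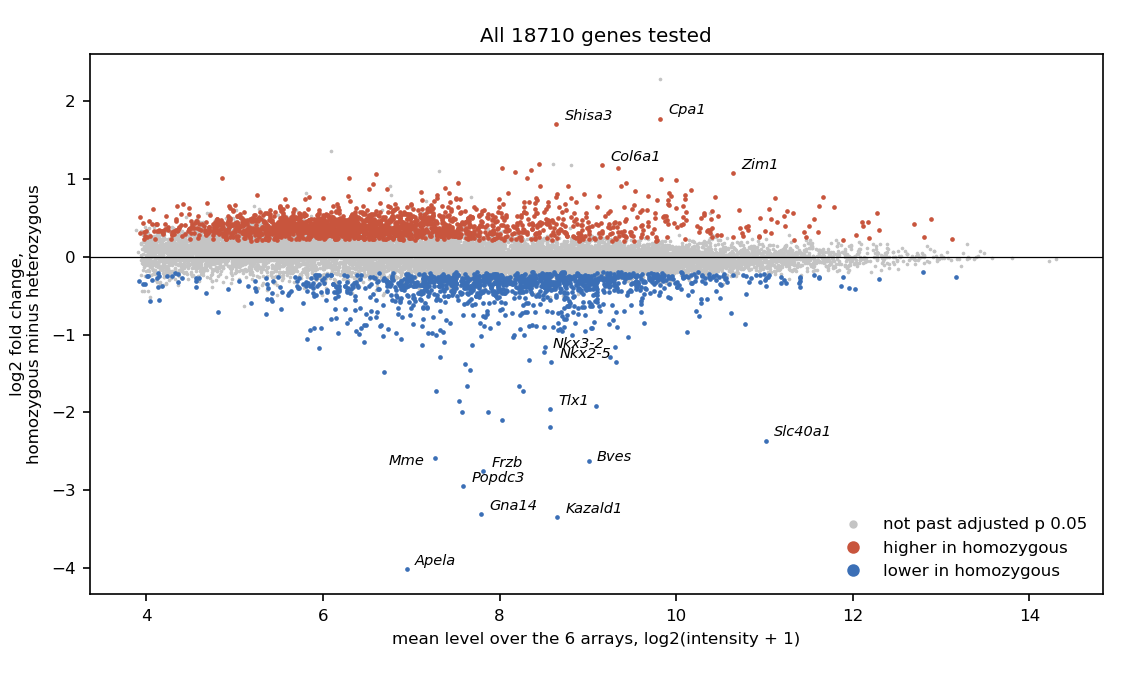
Log2 fold change (homozygous minus heterozygous) of 18710 genes against mean log2(intensity + 1) over the 6 arrays. Each point is a gene, red where higher and blue where lower at an adjusted p below 0.05, and grey otherwise. The falls reach −4.01 (Apela) and the called rises 1.77 (Cpa1), and dim genes lie mostly above 0.

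Among genes of retinoic acid metabolism and response more rose than fell. Of the Cyp26 degrading enzymes only Cyp26b1, which fell, kept its call in every refit without 1 array. Cyp26b1, which clears retinoic acid, fell from 442 ± 71.5 to 236 ± 18.2 (SD, n = 3), a log2 fold change of −0.89 ± 0.12 (adjusted p = 0.0029). The dim Cyp26c1, of the same enzyme family and chosen after its values were seen, was at 0.32 ± 0.09 (adjusted p = 0.0419), a call lost in all refits without 1 array but that without homozygous replicate 2 (0.23 to 0.37), after cyclic loess (0.18) and with the Y-linked level as a covariate (0.24). Rarb, a retinoic acid receptor and itself a direct target of the pathway, rose by 0.57 ± 0.07 (adjusted p = 0.00251). Rises were also seen in Adh1 (0.51 ± 0.06), an alcohol dehydrogenase that oxidises retinol, in Dhrs3 (0.45 ± 0.08), which turns retinal back into retinol, and in Crabp2 (0.43 ± 0.09), which carries retinoic acid to its receptors. The adjusted p of Dhrs3 was 0.074 and that of Crabp2 0.113 with the Y-linked level as a covariate. Aldh1a2, the synthesising dehydrogenase, had a log2 fold change of 0.23 ± 0.07 (adjusted p = 0.0537) and Rdh10, which makes retinal, one of −0.19 ± 0.07 (adjusted p = 0.0759). Both lay near the threshold without passing. Aldh1a2 passed under 7 other settings (adjusted p = 0.0421 after cyclic loess) and without homozygous replicate 3 (0.29), and Rdh10 under 3 (adjusted p = 0.0191 with a variance trend). Cyp26a1 (−0.10, adjusted p = 0.566) and the binding protein gene Crabp1 (0.10, adjusted p = 0.432) did not pass, and their groups overlapped. Cyp26a1 turned sign without heterozygous replicate 1 (0.02, and down to −0.19 without heterozygous replicate 2) and with the Y-linked level as a covariate (0.01), and was at −0.24 after cyclic loess. Crabp1 ranged from 0.03 without homozygous replicate 3 to 0.14 without heterozygous replicate 2, and was at 0.15 after cyclic loess and near 0 with the covariate.

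Of 28 measured genes of retinoic acid metabolism and receptors, 8 rose and 1 fell (11 and 2 adjusted over the list alone). Their median log2 fold change was 0.14 and the camera adjusted p = 0.0104, against an adjusted p = 0.412 with an estimated correlation. The adjusted p was 0.0625 without heterozygous replicate 3 (median 0.12) and 0.0823 with the Y-linked level as a covariate, and the median was 0.09 after cyclic loess. Among 30 retinoic acid responsive genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.20. That list had a camera adjusted p = 0.000231 and an adjusted p = 0.101 with an estimated correlation. Besides Rarb its largest rises were those of the Hox genes Hoxb5 (0.73) and Hoxa2 (0.54), and Cyp26b1 was its 1 fall. The lists share members and are not independent. Markers of epithelium, pancreas and enteric neurons were higher in the same samples (medians 0.30, 0.34 and 0.37).

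**Figure D2:**
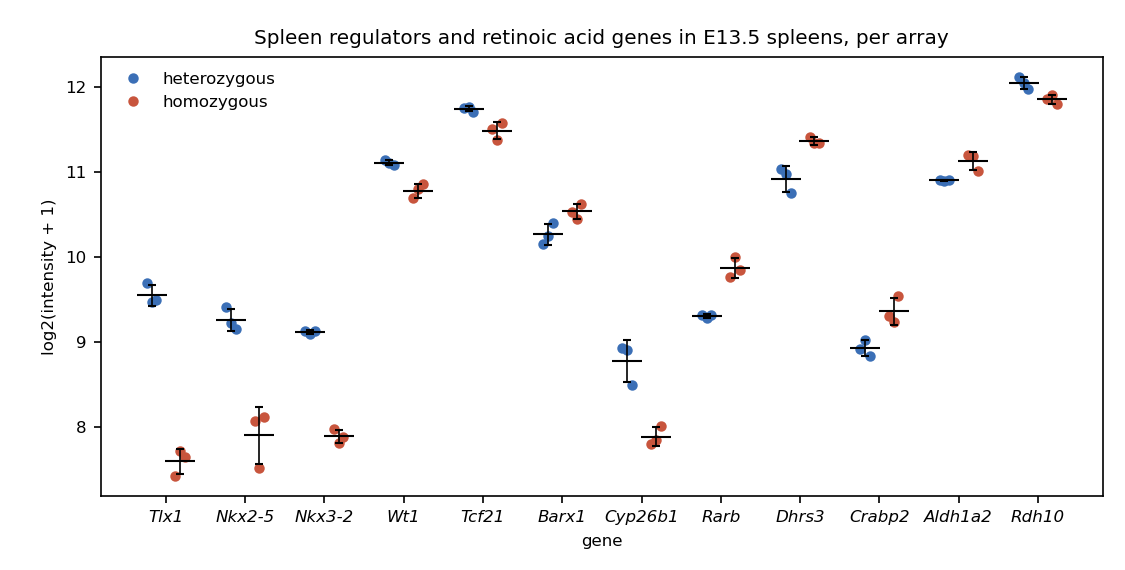
Levels of spleen regulators and retinoic acid genes as log2(intensity + 1) on each array. Points are arrays (blue heterozygous, red homozygous, 3 each), bars are means with SD. Tlx1, Nkx2-5, Nkx3-2 and Cyp26b1 were lower and Rarb higher in homozygous spleens. The groups overlapped for none of the genes shown, and Barx1, Aldh1a2 and Rdh10 did not pass the test.

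Transcription factors on the spleen list moved in both directions. Nkx2-5 fell from 614 ± 57.4 to 243 ± 52.8 (SD, n = 3; log2 fold change −1.36 ± 0.15) and Nkx3-2, which patterns the spleno-pancreatic mesenchyme, from 555 ± 8.19 to 236 ± 13.1 (SD, n = 3; −1.23 ± 0.06). Wt1 (−0.33 ± 0.06, adjusted p = 0.0133) and Tcf21 (−0.26 ± 0.07, adjusted p = 0.0359), both needed for the spleen to form, fell slightly. The call of Wt1 was lost without homozygous replicate 1 (−0.29) and with the Y-linked level as a covariate (adjusted p = 0.0593). Tcf21 lost its call in 5 of the 6 refits without 1 array (all but homozygous replicate 3; −0.30 to −0.21) and after cyclic loess (adjusted p = 0.0503). Ebf2 rose from 54.5 ± 2.72 to 110 ± 4.4 (SD, n = 3). Barx1, a regulator of stomach and spleen mesenchyme, was at 0.27 ± 0.08 (adjusted p = 0.0517), and passed under 8 other settings (adjusted p = 0.0405 after cyclic loess), without heterozygous replicate 3 (0.34) and without homozygous replicate 2 (0.32). In all, 7 of 22 list members rose and 6 fell (11 and 6 adjusted over the list alone). The falls include Tlx1 itself, altered by design, and the rises include Gata4, Isl1 and Klf4, which are also on the epithelium, pancreas and immediate early lists. The list had no shared direction in camera (adjusted p = 0.302), although it passed as higher after cyclic loess (adjusted p = 0.0306).

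Among Hox genes, which set position along the body axis, more rose than fell. Of 33 measured members 14 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.26 (0.17 after cyclic loess), a camera adjusted p = 1.68e-06 and an adjusted p = 0.101 with an estimated correlation. Hoxb5 rose by 0.73 ± 0.07, Hoxc4 by 0.70 and Hoxc6 by 0.63. Hoxd8 was the exception (−0.66). The medians of epithelium, pancreas and enteric markers were also above 0 in these samples (0.30, 0.34 and 0.37).

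Among cell cycle genes only falls passed, and these were small. Of 27 genes of G2/M and mitosis 15 fell and none rose (24 and 0 adjusted over the list alone), all 27 estimates were below 0, and the median was −0.25. After cyclic loess 7 fell, with a median of −0.21. Camera gave an adjusted p = 7.85e-11 for this list and an adjusted p = 0.108 with an estimated correlation. The 4 members with the largest falls were the motor protein gene Kif11 (−0.42), the kinase gene Nek2 (−0.40) and the spindle checkpoint kinase genes Ttk (−0.35) and Bub1 (−0.34). Among 29 genes of G1/S and replication 5 fell and none rose (7 and 0 adjusted over the list alone), with a median of −0.13 (3 falls and −0.08 after cyclic loess; camera adjusted p = 0.000148, adjusted p = 0.101 with an estimated correlation). They included the replication factor genes Gins1 (−0.38), Cdc6 (−0.38) and Pola1 (−0.36) and the cyclin gene Ccne2 (−0.34). These single calls were fragile. Without homozygous replicate 1 the calls of Kif11, Bub1, Ttk, Gins1, Cdc6, Pola1 and Ccne2 were lost, those of Kif11 and Pola1 in every such refit but that without homozygous replicate 2, those of Bub1 and Cdc6 also without heterozygous replicate 2 or 3 or homozygous replicate 3, and that of Ccne2 also without any 1 heterozygous array, with estimates that stayed between −0.54 and −0.26. After quantile normalization Cdc6 and Pola1 lost their calls (adjusted p = 0.0528 and 0.0594). Erythroid and endothelium markers were lower in the same samples (median −0.33 each).

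Endothelial markers that passed were mostly lower in homozygous spleens, and among markers of red cells and platelets only falls passed. Of 27 endothelium markers 18 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of −0.33, a camera adjusted p = 7.85e-11 and an adjusted p = 0.108 with an estimated correlation. The receptor gene Tek fell from 721 ± 34.5 to 401 ± 24.5 and Cd34 from 1600 ± 18.1 to 943 ± 45.5 (SD, n = 3), and Mmrn1 fell by 0.70. Lyve1, a marker of lymphatic endothelium and of some macrophages, rose by 0.59 ± 0.12 (adjusted p = 0.072 with the Y-linked level as a covariate). Among 19 erythroid markers 7 fell and none rose (13 and 0 adjusted over the list alone), with a median of −0.33 (camera adjusted p = 7.02e-07, adjusted p = 0.226 with an estimated correlation). The embryonic globin gene Hbb-bh1 fell by 1.06 ± 0.11, the heme synthesis gene Alas2 by 0.72, the membrane protein gene Rhag by 0.91 and Epb42 by 0.69. Rhag lost its call without homozygous replicate 1 or 3 (−1.06 to −0.67 over all 6 refits), and Epb42 without heterozygous replicate 2 or 3 or homozygous replicate 1 or 3 (−0.83 to −0.51). Of 8 megakaryocyte and platelet markers 3 fell and none rose (4 and 0 adjusted over the list alone), with a median of −0.19 (camera adjusted p = 0.000971, adjusted p = 0.407 with an estimated correlation). The platelet chemokine gene Ppbp fell by 1.73 ± 0.27 and Clec1b by 0.67, while Gp5 (−0.33) lost its call without heterozygous replicate 2 or homozygous replicate 1 (−0.38 to −0.28 over all 6 refits). Epithelium, pancreas and enteric markers lay the opposite way in these samples (medians 0.30, 0.34 and 0.37).

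White cell lists did not pass as a whole. None of 24 macrophage and myeloid markers passed, over all genes or adjusted over the list alone, and 3 had an unadjusted p below 0.05. The list median was 0.09 (camera adjusted p = 0.601), with Mrc1 at 0.27 (adjusted p = 0.0574) and Lyz2 at −0.27 (adjusted p = 0.136) nearest the threshold. Mrc1 passed under 7 other settings (adjusted p = 0.0371 after cyclic loess) and without homozygous replicate 3 (0.34), and Lyz2 passed with array weights (−0.36, adjusted p = 0.0387). Among 14 lymphoid and progenitor markers 3 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.332). The stem cell factor receptor gene Kit fell by 0.72 and Id2, an inhibitor of bHLH factors, rose by 0.52. The T cell genes Cd4 (0.47) and Cd3e (0.32) were dim, at 35.3 ± 3.08 and 80.0 ± 4.42 in homozygous spleens (SD, n = 3). After cyclic loess neither passed. Cd3e lost its call without heterozygous replicate 2 or homozygous replicate 1 (0.29 to 0.36 over all 6 refits), and Cd4 also without heterozygous replicate 1 or homozygous replicate 3 (0.37 to 0.59).

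Among genes of the Wnt and of the BMP and TGF-beta pathways more rose than fell. Of 30 Wnt pathway genes 14 rose and 1 fell (18 and 3 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 1.94e-05, adjusted p = 0.103 with an estimated correlation). The rises included the secreted antagonists Dkk2 (0.59) and Sfrp1 (0.58) and the receptor Ror1 (0.52), and the fall was that of the agonist Rspo3 (−0.59), so the members that moved include inhibitors and activators of the pathway. The antagonist gene Frzb (−2.75) and Shisa3 (1.70), named above, are outside this list. Of 26 BMP and TGF-beta genes 12 rose and 2 fell (13 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000445, adjusted p = 0.21 with an estimated correlation). The ligand gene Bmp5 rose by 0.62, the target genes Id3 and Id2 by 0.61 and 0.52, and Msx2 by 0.60. In the same samples epithelium, pancreas and enteric markers were higher by as much or more (medians 0.30, 0.34 and 0.37), and endothelium and erythroid markers were lower (−0.33 each).

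Notch, FGF and Hedgehog lists did not pass camera. Of 16 Notch genes 2 rose and 6 fell (3 and 7 adjusted over the list alone; median −0.05, camera adjusted p = 0.0992), and the list passed without homozygous replicate 3 (median −0.10, adjusted p = 0.0297). The fringe gene Lfng fell by 0.90 and the target Hes1 by 0.61, while Notch4 (−0.33) and Mfng (−0.29) lost their calls in all refits without 1 array but that without homozygous replicate 3 (−0.43 to −0.25 and −0.36 to −0.23). Of 18 FGF genes 1 rose and 5 fell (3 and 6 adjusted over the list alone). Their median was 0.07 while their mean was −0.06 and the camera test pointed down (adjusted p = 0.404). The receptor Fgfr4 (−0.49), the effector Etv1 (−0.45) and the feedback inhibitors Dusp6 (−0.34) and Spry4 (−0.28) fell. Each of these 4 calls was lost without at least 1 array (Fgfr4 without homozygous replicate 3, −0.57 to −0.39 over all 6 refits; the others without heterozygous replicate 1 or homozygous replicate 1 among others, −0.53 to −0.26). Of 14 Hedgehog genes 5 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.27, camera adjusted p = 0.0841), and the list passed without homozygous replicate 2 (median 0.34, adjusted p = 0.0399) and after cyclic loess (median 0.14, adjusted p = 0.0319). The co-receptor genes Boc and Gas1 rose by 0.43 and 0.39, and the ligand genes Ihh (0.41) and Shh (0.40) rose with calls lost without heterozygous replicate 1 or 2 or homozygous replicate 1 or 3, and for Ihh heterozygous replicate 3 (0.33 to 0.54 and 0.30 to 0.51 over all 6 refits). In the same samples endothelium markers were lower (median −0.33) and epithelium markers higher (median 0.30).

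Stromal and matrix genes moved in both directions. Of 24 genes of the spleen stroma and lymphoid niche 6 rose and 4 fell (7 and 4 adjusted over the list alone; median 0.07, camera adjusted p = 0.722). Kitl, the ligand of Kit, fell from 583 ± 4.82 to 301 ± 30.7 (SD, n = 3; −0.96 ± 0.08) and the adhesion molecule gene Madcam1 fell by 0.80, while Vcam1 rose by 0.72 and the chemokine gene Cxcl12 by 0.51. Of 35 extracellular matrix genes 10 rose and 8 fell (11 and 10 adjusted over the list alone; median 0.10, camera adjusted p = 0.41, and 0.03 after cyclic loess). Beside the collagen VI rises, the elastic fibre gene Fbln5 fell by 0.75 and the laminin gene Lama2 by 0.55. Of 17 smooth muscle markers 4 rose and 2 fell (5 and 4 adjusted over the list alone; median 0.17, camera adjusted p = 0.627), among them Des (0.64), Lmod1 (0.40), Csrp1 (−0.73) and Synpo2 (−0.46). Lmod1 lost its call without heterozygous replicate 2 or homozygous replicate 1 or 3 (0.36 to 0.48 over all 6 refits). Of 18 mesothelium markers Msln rose (0.47) and Wt1 fell (3 and 1 adjusted over the list alone; median 0.05, camera adjusted p = 0.861).

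Markers of epithelium and pancreas, beside the spleen, rose more often than they fell in homozygous samples. All 25 epithelium and stomach markers had estimates above 0, and 8 rose (18 adjusted over the list alone) with a median of 0.30, against 5 rises and a median of 0.21 after cyclic loess. That list had a camera adjusted p = 7.02e-07 and an adjusted p = 0.226 with an estimated correlation. The tight junction genes Cldn6 (0.88) and Cldn3 (0.61), Gata4 (0.61) and Spint1 (0.47) led it. Cldn6 lost its call without heterozygous replicate 2 or 3 or homozygous replicate 1 or 3 (0.63 to 1.13 over all 6 refits) and with a variance trend and a robust fit together (adjusted p = 0.0748), Spint1 without heterozygous replicate 2 or homozygous replicate 1 or 3 (0.35 to 0.56), and Gata4 with the Y-linked level as a covariate (adjusted p = 0.0558). Of 21 pancreas markers 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.34 (2 rises and 0.21 after cyclic loess; camera adjusted p = 0.00227, adjusted p = 0.491 with an estimated correlation, fry adjusted p = 0.109). Beside Cpa1 these rises included Isl1 (0.56), Nkx6-1 (0.42) and Rbpjl (0.35), transcription factors of islet and acinar cells. Isl1 is also a member of the list of spleen transcription factors. Nkx6-1 lost its call in all refits but that without homozygous replicate 2 (0.31 to 0.50), and Rbpjl without heterozygous replicate 1 or 2 or homozygous replicate 1 or 2 (0.29 to 0.42).

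Of 19 enteric neuron and glia markers 9 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.37 (0.23 after cyclic loess; camera adjusted p = 8.84e-05, adjusted p = 0.226 with an estimated correlation). The neuronal genes Stmn2 and Gap43 rose by 0.81 and 0.75 and the glial factor Sox10 by 0.57, a call lost without heterozygous replicate 1 or homozygous replicate 1 or 3 (0.39 to 0.71 over all 6 refits). Fabp7, a fatty acid binding protein gene of glia, fell by 1.38 ± 0.13. Of 14 adrenal and gonad markers 2 rose and none fell, likewise adjusted over the list alone. They were Gata4 and the dim Cyp11a1 (0.39), with a list median of 0.16 (camera adjusted p = 0.0313, adjusted p = 0.226 with an estimated correlation, 0.183 after cyclic loess, 0.058 after quantile normalization, 0.0689 without heterozygous replicate 2 and 0.0625 without heterozygous replicate 3). Cyp11a1 lost its call without heterozygous replicate 1 or 2 or homozygous replicate 1 or 3 (0.33 to 0.49 over all 6 refits). None of 15 liver markers passed, over all genes or adjusted over the list alone (2 had an unadjusted p below 0.05; median 0.06, and −0.07 after cyclic loess; camera adjusted p = 0.947). Nearest were Ambp at 0.76 (adjusted p = 0.0671), which passed under 4 other settings (adjusted p = 0.0412 with array weights), without heterozygous replicate 1 (1.05) and without homozygous replicate 2 (0.96), and Apoh at 0.26 (adjusted p = 0.108), which passed without heterozygous replicate 2 (0.37).

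**Figure D3:**
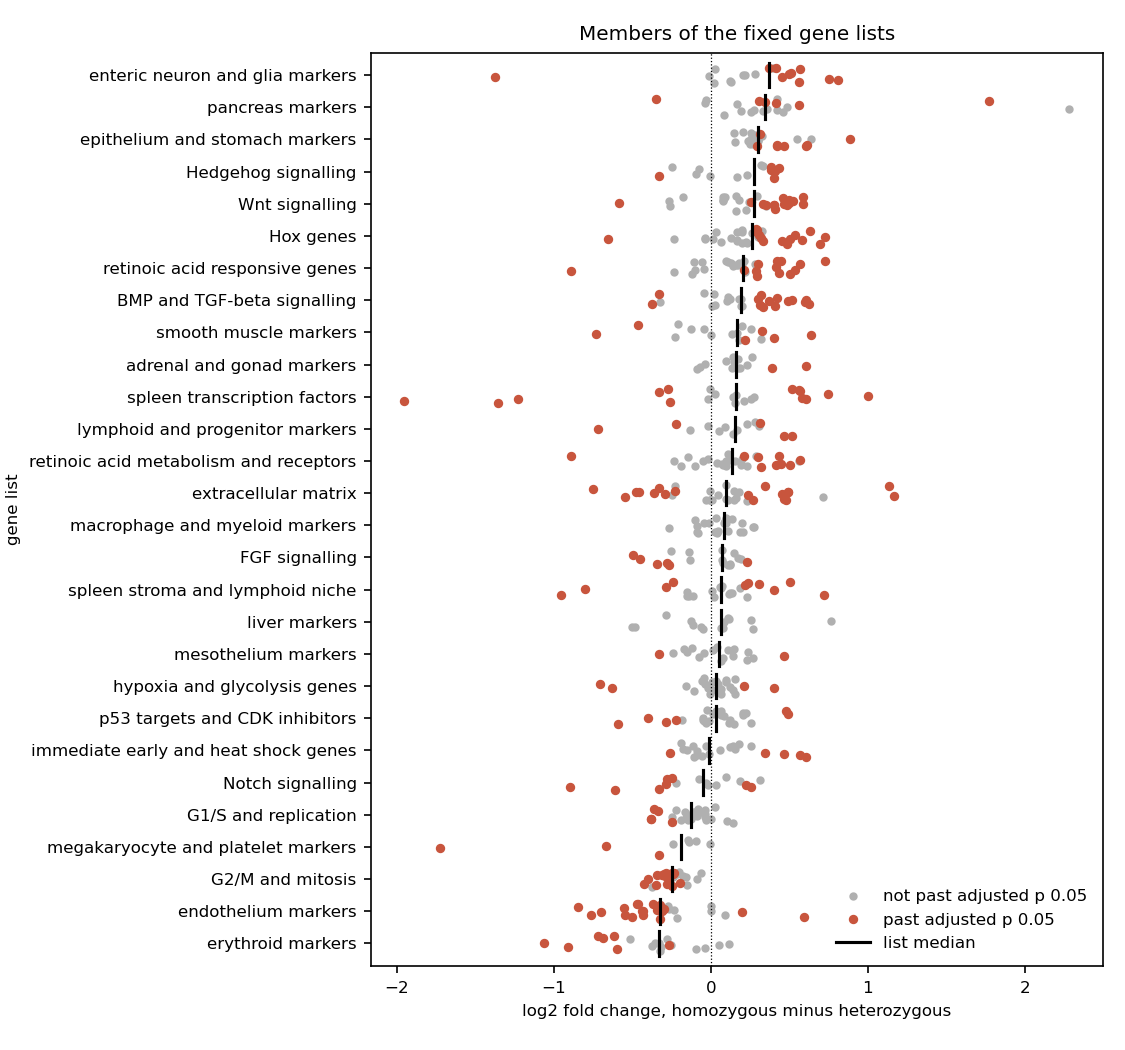
Log2 fold changes (homozygous minus heterozygous) of the measured members of 28 gene lists, ordered by list median. Red points are genes past an adjusted p of 0.05, grey points are the others, and black bars are medians. Medians run from −0.33 for erythroid and endothelium markers to 0.37 for enteric neuron and glia markers.

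Lists of stress and growth arrest had no shared direction. Of 25 p53 targets and CDK inhibitors 2 rose and 4 fell, likewise adjusted over the list alone (median 0.03, camera adjusted p = 0.947). The kinase inhibitor gene Cdkn1c, which is imprinted, rose by 0.48 and Plk2 by 0.49, while Phlda3 fell by 0.59 and the survival gene Bcl2 by 0.40. Of 21 immediate early and heat shock genes 4 rose and 1 fell, likewise adjusted over the list alone. Jun rose by 0.60, Klf4 by 0.57, Fosb by 0.47 and Hspa1a by 0.35, and the median (−0.01) differed in sign from the mean and the camera test (0.08, adjusted p = 0.722). Hspa1a lost its call without heterozygous replicate 2 or homozygous replicate 1 (0.30 to 0.40 over all 6 refits). Of 24 hypoxia and glycolysis genes 2 rose and 2 fell, likewise adjusted over the list alone, and their median was 0.03 and their mean −0.01, with a camera test pointing up (adjusted p = 0.947). Vegfa, the main endothelial growth factor, fell from 988 ± 48.0 to 607 ± 58.7 (SD, n = 3; −0.71 ± 0.08) and the glycolysis regulator Pfkfb3 by 0.63, P4ha2 rose by 0.41 and Tpi1 by 0.21. Tpi1 lost its call in all refits but that without homozygous replicate 2 (0.19 to 0.23). None of the 4 measured sex-linked genes passed. Eif2s3y was at −0.48 (adjusted p = 0.107) and Kdm5d at −0.47 (adjusted p = 0.129), and both passed without heterozygous replicate 2 (−0.73 and −0.74), and Eif2s3y with a variance trend (adjusted p = 0.0492).

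Of the 28 lists tested, 14 passed camera at the preset correlation, 9 higher and 5 lower, and none passed with an estimated correlation, where the smallest adjusted p was 0.101. For retinoic acid responsive genes, Hox and G1/S the estimate was below the preset 0.01 (−0.027, −0.0013 and −0.015). A larger correlation therefore did not end those calls. This form of camera also uses the few residual degrees of freedom of 6 arrays. For the other lists that passed the estimate was above 0.01, up to 0.57 for megakaryocyte and platelet markers. Fry, which asks whether the members of a list move one way on balance, passed 15 lists, and 26 passed its test for change in either direction. Among the genes named with the lists, cyclic loess ended the calls of Cd3e, Cd4, Cdc6, Cyp11a1, Dusp6, Fosb, Kif11, Lmod1, Nkx6-1, Pola1, Rbpjl, Shh, Sox10, Spint1, Tcf21 and Tpi1 (adjusted p from 0.0503 to 0.149). The log2 fold change was nearly unmoved for Tpi1 (0.21 ± 0.06 before and after) and Tcf21 (−0.26 ± 0.07 and then −0.25 ± 0.07), and shrank for Cd3e (0.32 ± 0.07 and then 0.18 ± 0.07), Shh (0.40 ± 0.12 and then 0.27 ± 0.10) and Rbpjl (0.35 and then 0.23). The Y-linked level as a covariate, in a fit with 1 fewer residual degree of freedom, ended those of Bcl2, Bub1, Ccne2, Cd3e, Cdc6, Dusp6, Epb42, Etv1, Fgfr4, Fosb, Gas1, Ihh, Kif11, Mfng, Nek2, Notch4, Pola1, Rhag, Shh, Spry4, Tcf21, Tpi1 and Ttk (adjusted p from 0.0508 to 0.224), beside those of Crabp2, Dhrs3, Gata4, Lyve1, Olfr59 and Wt1 given above. Of these 29 genes 8 had a larger log2 fold change with the covariate (Shh 0.40 ± 0.12 and then 0.55 ± 0.14, Ihh 0.41 ± 0.11 and then 0.50 ± 0.14) and 21 a smaller one (Rhag −0.91 ± 0.19 and then −0.69 ± 0.23), while the SE grew for all, by 1.20 to 1.45 times. The move was below 1 SE of the covariate fit for 28 of the 29. Quantile normalization ended the calls of Mfng, Notch4, Shh and Spry4 (adjusted p from 0.0553 to 0.0869), median centring those of Mfng and Notch4 (0.0574 and 0.0547) and the fit with no filter those of Mfng and Shh (0.0504 and 0.0539). Medians of lists that did not pass also moved with cyclic loess, to 0.06 for smooth muscle, 0.02 for lymphoid and 0.04 for macrophage markers, −0.12 for Notch and 0.03 for FGF genes.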

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

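The splits of the 6 arrays were planned. The tests on probe sets outside the comparison of genes, on cyclic loess, on lists matched by level, on neighbouring tissues and on imprinted genes were chosen only after the results were seen.

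Some calls appeared in data that the report's comparison does not use, the probe sets with several gene symbols or none. Of 11596 such probe sets 25 passed an adjusted p of 0.05 in a separate limma fit, 23 lower and 2 higher in homozygous spleens. Of them 12 carried several symbols and 13 were unnamed. The Mir467 family accounts for 9, which hold identical values (−1.11) and are 1 measurement, on average below the filter floor in homozygous spleens. The adjustment counted these 9 copies as separate tests, which lowers the adjusted p of the other calls too (0.0372 to 0.0452). An adjustment that counts them once was not made, so none of the 25 calls is secure. The probe set shared by Ly6c1 and Ly6c2 was at −1.60.

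More genes were called higher (1951) than lower (1227), and dim genes leaned upward. After cyclic loess, which removes any trend with level whatever its source, 48.3% of calls were higher. A near even share follows from that step, so it cannot tell an offset left by the normalization from an effect of genotype. An offset with level was argued against as the whole source of the list calls at the preset correlation. There 13 of the 14 lists still passed camera with the same direction (adrenal and gonad markers were lost). With an estimated correlation none had passed before cyclic loess. Medians shrank for Hox from 0.26 to 0.17, pancreas from 0.34 to 0.21, enteric from 0.37 to 0.23, retinoic acid metabolism from 0.14 to 0.09 and G1/S from −0.13 to −0.08. Falls in G2/M went from 15 to 7, so an offset may carry a part of these. Medians grew for erythroid markers (−0.33 to −0.45), BMP and TGF-beta genes (0.20 to 0.23) and megakaryocyte markers (−0.19 to −0.22). Whether genotype itself lowers bright and raises dim transcripts was not tested. The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05, and 1 of 10, the real one, gave as many higher genes (highest other 0), lower genes (highest other 0), genes changed at least 2-fold (highest other 0) and lists past camera (14, highest other 10). Every other split mixes the genotypes within its groups, so the genotype difference adds to its spread. Its counts therefore do not show what chance alone would give.

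Epithelium and stomach markers were higher in homozygous spleens as a set at the preset correlation (median 0.30, camera adjusted p = 7.02e-07). With an estimated correlation the camera adjusted p was 0.226. The central 95% of 10000 random lists matched on size and level had medians of at most 0.179. Were the members independent, this would argue against the offset with level as the whole of it. Their estimated correlation was 0.25, which the matched lists do not allow for. Whether the homozygous samples held more neighbouring epithelium was not decided, since 100% of the 25 members had positive estimates both before and after cyclic loess. For the pancreas markers that share was 85.7% both times, which did not decide either, and the hormone gene Gcg (chosen after its values were seen) varied within groups, at 98, 659 and 1032 on heterozygous and 3751, 761 and 2728 on homozygous arrays. A change of gene expression within the spleen itself stays open, as untested.

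Among imprinted genes, a list of 52 written after the data were seen, more rose than fell in homozygous spleens. Of 44 measured, 18 rose and 2 fell (24 and 2 adjusted over the list alone), with a median of 0.18 against at most 0.0416 for the central 95% of lists matched on level, and 0.15 after cyclic loess, so the offset with level is argued against. Dlk1 (0.77), Peg3 (0.63) and Zim1 (1.07) rose, and Sfmbt2 fell (−1.46). Zim1, seen among the largest rises before the list was written, is counted in it. Imprinted genes of 1 cluster can move together, so the members are not independent, which the matched lists do not allow for. A shared rise of the class may be present, but its camera p was 1.94e-05 at the preset correlation and 0.0576 with an estimated one, which leaves this open. Differences in cell makeup between the groups were not tested for these genes, and marker lists moved by as much or more in the same samples (medians 0.30 for epithelium, 0.34 for pancreas, 0.37 for enteric, and −0.33 each for endothelium and erythroid markers).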

How the results depend on the processing

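The fits with the Y-linked gene level and with cyclic loess were chosen after seeing the data, the others before. No list or named gene reversed a call. The balance of calls did turn, from 1951 higher and 1227 lower genes to 1092 and 1168 after cyclic loess. Tlx1 kept its call throughout (−2.02 to −1.87), and genes changed at least 2-fold ranged from 54 to 77. Leaving out 1 array gave 699 (without homozygous replicate 1) to 2319 (without homozygous replicate 2) higher genes and 499 to 1244 lower genes for the same arrays; fewer samples enter these fits. The Y-linked level as a covariate gave 1140 and 507, and cyclic loess 1092 higher genes. The replicate block gave 2091 higher and 1072 lower genes and 59 changed at least 2-fold. Same-numbered arrays' deviations correlated at −0.01, 0.04 and −0.11, which shows no pairing by number and does not exclude one. The replicate block ended the calls of Mfng, Tcf21 and Tpi1, gave calls to Ambp and Barx1, and changed no other named gene or list.

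Without 1 array, list medians ranged from 0.12 to 0.17 for retinoic acid metabolism (lost without heterozygous replicate 3), 0.18 to 0.34 for Hedgehog (gained without homozygous replicate 2), −0.10 to −0.037 for Notch (gained without homozygous replicate 3) and 0.14 to 0.18 for adrenal and gonad markers (lost without heterozygous replicate 2 or 3). Among other lists that did not pass, medians moved by over 1.5 times in at least 1 refit for matrix (0.043 to 0.11), smooth muscle (0.090 to 0.19), lymphoid (0.092 to 0.21), macrophage (0.018 to 0.098), p53 (0.019 to 0.060) and hypoxia genes (0.0058 to 0.056), and turned sign for FGF (−0.00094 without heterozygous replicate 1, otherwise up to 0.094), mesothelium (−0.0013 without heterozygous replicate 3, otherwise up to 0.071), liver (−0.051 to 0.14) and immediate early genes (−0.045 to 0.024). With an estimated correlation 0 lists passed, with unmoved medians for retinoic acid metabolism (0.14) and responsive genes (0.20), Hox (0.26), G1/S (−0.13), G2/M (−0.25), Wnt (0.27), BMP (0.20), endothelium (−0.33), erythroid (−0.33), megakaryocyte (−0.19), pancreas (0.34), epithelium (0.30), enteric (0.37) and adrenal markers (0.16). Fry gave a call to stroma (0.068) and Hedgehog (0.27) and not to pancreas (0.34). Adrenal markers were lost after quantile normalization (0.19) and cyclic loess (0.071), which gave a call to spleen transcription factors (0.18), matrix (0.14) and Hedgehog (0.14). With the Y-linked level retinoic acid metabolism was lost (0.17). The cause of these changes was not tested.

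Of 117 named genes past the threshold 86 kept the call in all 6 refits without 1 array. Cyclic loess ended 16 calls among 127 named genes and gave 3, and the Y-linked level ended 29. Leaving out probe sets by ID ending was not run, since the IDs are numeric. Dim probe sets near the background limit the size of measurable changes.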

Other observations

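The test on gene neighbours was chosen only after the result was seen.

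Genes changed at least 2-fold included pairs that lie side by side in the gene order of the assembly GRCm38.p6. Popdc3 (−2.94) and Bves (−2.62), Kazald1 (−3.34) and Tlx1 (−1.95), and Clca3a1 (−2.18) and Clca3a2 (−2.09) fell together, and Col6a1 (1.17) and Col6a2 (1.14) rose together. So did, among genes chosen after their values were seen, falls of the glutamate receptor gene Grm7 (−1.66) with Lmcd1 (−1.01) and of the neural adhesion genes Opcml (−1.16) and Ntm (−1.16). The 58 genes held 6 such pairs. In 10000 random sets of 58 of the 18636 placed genes there were 0.174 on average and 3 at most (permutation p = 1e-04, the smallest these draws can give). The random sets treat every gene as a separate measurement, which Clca3a1 and Clca3a2 may not be. The pairs also include Tlx1, altered by design, and were seen before the test was chosen. The permutation p therefore holds for 58 separate genes and does not decide whether unrelated neighbours move together. Probes shared between paralogs, which Kazald1 with Tlx1 and Grm7 with Lmcd1 are not, and shared regulation of neighbours were not tested.

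Among the 50 measured genes nearest Tlx1, 25 on each side, 7 were called (14%, against 17.0% of all genes) and 1, Kazald1, changed at least 2-fold.

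Endothelium markers (median −0.33) and Vegfa (−0.71) were lower in the same samples, and so were Kit (−0.72) and its ligand gene Kitl (−0.96). The relation between the members of these pairs was not tested.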
